A study of Paralichthys olivaceus with 22 samples.

How the data were processed

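Kidney RNA of Japanese flounder (Paralichthys olivaceus) was measured on 22 custom Agilent oligonucleotide arrays in 7 groups. Control fish were not vaccinated (3 arrays), and no sampling day or dose is recorded for them here. The other groups received formalin-killed cells of Edwardsiella tarda into the muscle: a typical strain (UH6), an atypical strain (UT1) or an equal mixture of both, and were sampled after 3 or 7 days. There were 3 arrays per group and 4 for the mixture on day 7. Per the labels, replicates 1 and 2 of every group but the day 7 mixture held RNA pooled from 2 fish, and replicate 3 held RNA of a single fish. All 4 day 7 mixture arrays held single fish. The arrays were therefore separate fish or pools, 12 pools and 10 single fish. Groups were taken from the sample titles. The source name of day 7 mixture replicate 4 gives the typical vaccine, while its title and the design text give the mixture; it was kept as mixture, and the other reading was an alternative.

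Per the labels' protocols, total RNA was extracted with a column kit, reverse transcribed from an oligo(dT) primer carrying a T7 promoter, transcribed into Cy3-labelled cRNA and hybridised for 15 h at 65 °C. Scanning used an Axon GenePix scanner at 5 micrometres per pixel with 2 passes, per the file headers. The deposited scanner files hold Cy3 spot intensity from Agilent Feature Extraction (version 9.5 per the submitters' processing notes), which per the file headers was background-subtracted and detrended within the array and not normalized between arrays. Each array had 10593 spots, of which 536 were controls and 10057 were not, for 9877 distinct probes of 60 nt. A deposited table by the authors gives log2 values for 9937 entries. In all of these entries the median over the 3 control arrays was 0. With each entry centred on its median over the arrays, its values correlated with the scanner values scaled to the 75th percentile. The r was 0.997 over all entries and arrays together, so the direction is vaccinated over control. Other scalings were not set beside this r, and the authors' scaling between arrays is not given in the sources used here. The column medians of the authors' table were 0 for all 3 control arrays. For day 3 replicates 1 to 3 they were -0.16, -0.18 and -0.068 (typical), -0.12, -0.12 and -0.27 (atypical) and -0.097, -0.14 and -0.19 (mixture). For day 7 they were -0.016, -0.006 and -0.10 (typical), -0.010, -0.016 and -0.13 (atypical) and 0.034, 0.14, -0.092 and -0.063 (mixture, replicates 1 to 4). The second channel named in the labels is the control average and was not hybridised.

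The main values were log2 of the processed signal minus each array's 75th percentile of it over spots that are not controls. Control spots were left out, as were spots marked as outliers by the extraction software, which were 2.26% to 4.39% of spots per array; saturated spots were kept. Spots of the same probe were averaged. Probes well above background on at least 3 arrays were kept, which left 6729. Probes are identified by contig numbers (4726 forward and 4711 with the prefix rev_, here called the reverse orientation) or by GenBank accession (440 probes, 437 accessions). The files do not pair them with gene names. The accessions were looked up by exact text in the RefSeq gene table of assembly ASM2471397v2, and 0 of 437 were found. RefSeq numbers its records apart from GenBank, so this lookup could not be expected to map them. No sequence was compared. Probes are therefore reported by identifier and sequence, and no genome position is given. Without gene names, the 24 gene lists fixed before the data were examined could be given no members, and their tests were not run.

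Linear models were fitted with limma 3.58.1 in R 4.3.3 to all 22 arrays and 7 group means, with empirical Bayes moderation and Benjamini-Hochberg adjustment within each comparison at 0.05. A probe was tested in a comparison when each of its groups kept at least 1 value, which left 6416 to 6533 probes per comparison. Comparisons were each vaccinated group against control, the mixture against the mean of both single vaccines, atypical against typical, day 7 against day 3, and the difference of the mixture contrast between the days. The design, the alternatives and the naming rule were fixed before the data were examined. The rule for data without gene names takes the largest change among probes past the threshold, at most 2 higher and 2 lower per comparison. As applied, both in comparisons with control and between days, every array of 1 group had to lie on 1 side of every array of the other. Chance gives this pattern to 10% of unchanged probes with 3 against 3 arrays. Folds are antilogs of the difference of mean log2 values. Where a probe was not well above background on any array of a group, the fold is a bound, written "at least": the brighter group's mean against the mean of, per array, the higher of the probe's own value and the lowest signal among probes well above background.

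Several choices followed a look at the results. Counts were first seen with outlier spots kept, then with these left out and probes required to have a value in every group; the reported fit tests each probe wherever its own comparison has values. The naming rule was read as needing a value on every array of both groups after a probe with a single value in a group had topped lists. The alternatives with outlier spots kept, with at least 2 values in every group, within slide 1 or 2, and with slide as a block together with quantile normalization were added after seeing the data, as were slide as a block and kept outlier spots for the correlations between responses. The limits by which the explanations in the closing tests were judged were made stricter after a first run. The alternatives fixed before the data were examined were normexp background correction (offset 50) on mean and local background signals, quantile normalization, no filter or a filter for probes well above background on all arrays, a fit to the groups compared only, replicate number or slide as a block, weight 2 for pooled arrays, the authors' table, replicate 4 of the day 7 mixture moved to the typical group, and leaving out each array in turn.

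The arrays lay on 3 slides. Slide 1 held 8 arrays: replicates 1 and 2 of control and of the day 3 groups. Slide 2 held 7: replicates 1 and 2 of the day 7 groups and replicate 3 of the day 7 mixture. Slide 3 held 7: the remaining single-fish arrays, 1 per group. The 75th percentile signal was 4019 to 5067 on slide 1, 3096 to 4360 on slide 2 and 2889 to 3555 on slide 3. The share of probes well above background was 54.8% to 67.5% per array and that of saturated probes 4.14% to 6.78%. Precision is limited by the number of arrays. Over 18 probes printed 10 times, the median SD was 0.14 log2 between spots of an array. Between samples of a group it was 0.23 log2 for the means of these spots. Other probes have fewer spots, so 0.23 does not give their spread. Over all tested probes, the median SE of a difference from control was 0.30 to 0.32 log2. Correlations between arrays of a group were 0.948 to 0.986 across probes, and no pair of arrays was identical.

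Whether replicate numbers pair the samples was checked by correlating deviations from group means. Of 33 pairs, 20 were over 0.1 (range -0.541 to 0.389), and all 3 pairs were over 0.1 in 3 comparisons: typical against control on day 3 (0.276, 0.186 and 0.177), atypical against typical on day 7 (0.161, 0.339 and 0.201) and atypical on day 7 against day 3 (0.100, 0.242 and 0.306). Same-numbered samples are different fish, and the numbers follow slide and pooling.

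The fit was tested on simulated data, with 200 probes per comparison given a known change in the real design. For the comparisons with control, 32 to 46 of 100 probes changed by 1 log2 and 65 to 73 of 100 changed by 2 log2 were recovered, with 5 to 8 unchanged probes called. The simulated noise was independent between probes and arrays and held no slide or pool effects. These numbers therefore do not give the false calls to be met in the real arrays. Figures were drawn with matplotlib 3.10.9.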

Results

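Kidney RNA was compared between non-vaccinated Japanese flounder and fish that had received formalin-killed Edwardsiella tarda, the bacterium that causes edwardsiellosis in farmed fish. In bony fish the kidney is a main site of blood formation and of immune cells. Fish of 40 g, kept at 24 °C, received 100000000 killed cells of a typical strain, of an atypical strain, or of an equal mixture of both, and kidneys were taken after 3 or 7 days. The study set out to describe the response to the mixed vaccine beside those to its parts. Both days were compared with the same controls, which have no recorded sampling day. Differences from control therefore do not separate the vaccine from the injection itself or from sampling time. There were 22 arrays: 3 controls, 3 for each vaccine on day 3, 3 each for the typical and atypical vaccines on day 7, and 4 for the mixture on day 7. Between 5415 and 6666 of 9877 probes per array were well above background. Levels are log2 signals relative to the array's 75th percentile.

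On day 3 after the typical vaccine, the kidney differed from that of non-vaccinated fish at 991 of 6509 probes (limma, adjusted p under 0.05), 667 higher and 324 lower, and 647 of them changed at least 2-fold. POC02521_1 rose 35.3-fold, from -5.37 ± 0.67 to -0.23 ± 0.55 (SD, n = 3 each; log2 difference 5.14, SE 0.71, limma adjusted p = 3.10e-04), and was well above background on 2 of 3 controls; with normexp the log2 difference was 3.33. POC01779_1, not well above background on any control array, was at least 10.7-fold higher (log2 difference 4.93, SE 0.92, limma adjusted p = 0.00237). The largest falls were POC00967_1 (log2 difference -5.28, SE 1.57, limma adjusted p = 0.0321) and AB099302 (-5.17, SE 1.59, limma adjusted p = 0.0366). Both falls rested on a single control array: POC00967_1 was at 3.83 on control 1, where it was saturated, against -4.72 and -3.59 on the other controls, and AB099302 at 4.11, also saturated, against -3.59 and -2.65. On vaccinated arrays they were well above background on 1 and 2 of 3. Without control 1 the log2 differences were -2.62 and -2.76, and with normexp -3.62 and -3.59. Their adjusted p was 0.0560 to 0.175 without control 1 or without any 1 of the 3 vaccinated arrays, and 0.184 and 0.191 within slide 1. Of the probes called higher, 83 were not well above background on any control array. The probe sequences are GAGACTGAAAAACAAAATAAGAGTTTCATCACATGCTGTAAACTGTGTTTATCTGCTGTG for POC02521_1, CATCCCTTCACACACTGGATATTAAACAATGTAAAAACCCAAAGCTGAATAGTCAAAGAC for POC01779_1, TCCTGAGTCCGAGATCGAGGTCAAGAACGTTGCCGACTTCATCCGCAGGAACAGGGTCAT for POC00967_1 and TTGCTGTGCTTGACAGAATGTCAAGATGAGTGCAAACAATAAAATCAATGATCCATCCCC for AB099302. With slide as a block 1567 probes were called and within slide 1 alone 507; the fit to these 6 arrays called 215, the fit with weight 2 for pools 1522, and leaving out day 3 typical replicate 1 or 2 left 574 or 625. Normexp background correction moved the median of all probes to -0.25 and turned the split to 466 higher and 822 lower, and 580 of the 667 higher probes lay above 0 there; it also ended the call of POC01779_1 (log2 difference 1.71, under its bound, adjusted p = 0.0846).

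After the atypical vaccine, 1451 of 6477 probes differed from control on day 3, 957 higher and 494 lower, 903 of them at least 2-fold. POC05682_1 was higher (2.53 ± 1.72 against -3.29 ± 3.36 in controls, SD, n = 3 each; log2 difference 5.83, SE 1.74, limma adjusted p = 0.0242). It was saturated on vaccinated replicate 1 and not well above background on control 2, and its log2 difference ran from 4.46 without control 2 to 7.70 without control 1. POC02521_1 rose 25.4-fold (log2 difference 4.67, SE 0.71, limma adjusted p = 4.15e-04; 2.87 with normexp). POC03715_1 (log2 difference -5.43, SE 1.87, limma adjusted p = 0.0460) and POC00967_1 (-4.70, SE 1.57, limma adjusted p = 0.0412) were lower. On vaccinated arrays they were well above background on 1 and 0 of 3, so neither size is exact. POC03715_1, like POC00967_1, was saturated on control 1 (3.74) and far lower on the other controls (-5.04 and -2.02). POC05682_1 also varied among controls (0.45, -6.03 and -4.30). Without control 1 the log2 difference was -3.01 (adjusted p = 0.251) for POC03715_1 and -2.04 (adjusted p = 0.201) for POC00967_1; without control 2 it was -7.40 and -6.32. Both calls were also lost without any 1 of the vaccinated arrays, and that of POC03715_1 without control 3 (adjusted p 0.0635 to 0.141). POC05682_1 was not called without control 2 or 3 or vaccinated replicate 1 or 2 (0.0693 to 0.117), and within slide 1 none of the 3 passed (0.0904 to 0.292). The probe of POC05682_1 is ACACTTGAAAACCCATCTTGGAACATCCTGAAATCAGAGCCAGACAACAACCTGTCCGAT and that of POC03715_1 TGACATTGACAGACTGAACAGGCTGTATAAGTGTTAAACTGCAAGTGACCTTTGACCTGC. The count was 1865 with slide as a block, 834 within slide 1, 929 in the fit to these 6 arrays and 916 without atypical replicate 2. With normexp the median of all probes was -0.31 and the split 670 higher and 1465 lower, and 802 of the 957 higher probes lay above 0.

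After the mixture, 1715 of 6501 probes differed from control on day 3, 1038 higher and 677 lower, 1130 of them at least 2-fold. POC00929_1 was higher, going from -4.70 ± 3.17 to 2.77 ± 0.80 (SD, n = 3 each; log2 difference 7.47, SE 1.47, limma adjusted p = 0.00183). Controls were at -1.09, -7.03 and -5.98, and only the first was well above background, so the fold has no exact base. The log2 difference of POC00929_1 ran from 5.76 with normexp to 9.28 without control 1. POC05682_1 was also higher (log2 difference 6.07, SE 1.74, limma adjusted p = 0.0159; 4.70 without control 2 and 7.94 without control 1). POC03318_1 fell 26.9-fold, from 1.29 ± 1.10 to -3.46 ± 0.99 (SD, n = 3 each; log2 difference -4.75, SE 0.86, limma adjusted p = 0.00109). Over all alternatives and left-out arrays its log2 difference ran from -5.37 to -4.23. POC03318_1 belongs to a set of probes that varied together within groups, described at the end. POC04519_1 fell 26.8-fold, from 1.00 ± 1.43 to -3.74 ± 1.98 (SD, n = 3 each; log2 difference -4.75, SE 1.07, limma adjusted p = 0.00402), and was well above background on 2 of 3 vaccinated arrays; its log2 difference was -3.60 without mixture replicate 2 and -5.55 without control 1. POC00929_1, POC03318_1 and POC04519_1 passed with each single array left out; POC05682_1 did not without control 2 or 3 or mixture replicate 1 (adjusted p 0.0508 to 0.0848). The probes read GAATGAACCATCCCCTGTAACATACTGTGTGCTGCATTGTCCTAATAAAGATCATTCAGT for POC00929_1, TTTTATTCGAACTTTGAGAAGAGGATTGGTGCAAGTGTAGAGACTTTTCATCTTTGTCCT for POC03318_1 and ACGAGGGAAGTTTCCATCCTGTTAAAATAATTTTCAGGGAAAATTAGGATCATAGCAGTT for POC04519_1. The count was 2174 with slide as a block, 923 within slide 1 and 868 in the fit to these 6 arrays; within slide 1 the rises of POC00929_1 (7.29, adjusted p = 0.0935) and POC05682_1 (5.75, adjusted p = 0.111) and the fall of POC04519_1 (-5.12, adjusted p = 0.0989) did not pass. With normexp the median of all probes was -0.28 and the split 721 higher and 1450 lower. Of the 1038 higher probes 864 lay above 0 there, 662 were still called higher and 8 were called lower.

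On day 7 the typical vaccine differed from control at 298 of 6510 probes, 232 higher and 66 lower, 204 of them at least 2-fold. The named probes of this comparison all target the reverse orientation and were at background in 1 of the groups, so their folds are bounds. rev_POC03085_1 was at least 14.8-fold higher (log2 difference 5.21, SE 1.35, limma adjusted p = 0.0367) and rev_POC04042_1 at least 6.99-fold higher (3.75, SE 0.69, limma adjusted p = 0.00672). rev_POC00483_1 was at least 5.65-fold lower (-3.42, SE 0.52, limma adjusted p = 0.00183) and rev_POC02323_1 at least 2.86-fold lower (-3.41, SE 0.37, limma adjusted p = 1.54e-04). rev_POC02323_1 was well above background on all 3 controls, at -4.25 ± 0.91, and on no vaccinated array of this comparison. The call of rev_POC03085_1 was lost without any 1 of the 6 arrays (adjusted p 0.0575 to 0.127); the other 3 held. The probes read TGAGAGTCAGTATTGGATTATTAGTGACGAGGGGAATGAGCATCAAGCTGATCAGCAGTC for rev_POC03085_1, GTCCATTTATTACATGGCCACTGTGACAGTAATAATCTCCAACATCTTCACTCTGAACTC for rev_POC04042_1, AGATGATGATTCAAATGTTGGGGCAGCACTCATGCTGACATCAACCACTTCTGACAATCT for rev_POC00483_1 and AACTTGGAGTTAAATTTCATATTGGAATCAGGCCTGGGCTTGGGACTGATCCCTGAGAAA for rev_POC02323_1. A fit to these 6 arrays called 0 probes, with slide as a block 352 were called, with weight 2 for pools 488, with mixture replicate 4 counted as typical 719, and 198, 119 and 152 without control 1, 2 or 3 and 137 and 117 without typical replicate 2 or 3. With normexp the median of all probes was -0.21 and the split 129 higher and 196 lower, 195 of the 232 higher probes lay above 0, and neither rise named here passed (log2 differences 2.02 and 1.20, adjusted p 0.0815 and 0.138). The falls of rev_POC00483_1 and rev_POC02323_1 were -1.75 and -1.86 there, and of the 4 bounds only that of rev_POC02323_1 holds on that scale.

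The atypical vaccine on day 7 differed from control at 313 of 6503 probes, 243 higher and 70 lower, 199 of them at least 2-fold. rev_POC03085_1 was at least 14.2-fold higher (log2 difference 5.15, SE 1.35, limma adjusted p = 0.0341) and rev_POC04042_1 at least 8.49-fold higher (4.04, SE 0.69, limma adjusted p = 0.00240). rev_POC00483_1 was at least 5.87-fold lower (-3.94, SE 0.52, limma adjusted p = 5.48e-04). POC03134_1 fell 10.0-fold, from 2.81 ± 1.43 to -0.52 ± 0.96 (SD, n = 3 each; log2 difference -3.32, SE 0.57, limma adjusted p = 0.00240); its probe is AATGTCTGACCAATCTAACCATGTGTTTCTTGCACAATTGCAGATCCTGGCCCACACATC. Again rev_POC03085_1 was not called without any 1 of the 6 arrays (adjusted p 0.0522 to 0.105), while the other 3 were. The log2 difference of POC03134_1 ran from -4.38 to -2.75 over all alternatives and left-out arrays. The count was 504 with slide as a block, 560 with weight 2 for pools, 22 in the fit to these 6 arrays (of the named probes rev_POC03085_1 alone), 162 without control 2, and 178 and 170 without atypical replicate 2 or 3. Normexp called 506 probes, 189 higher and 317 lower, with a median of all probes of -0.22; 202 of the 243 higher probes lay above 0, and neither rise named here passed (log2 differences 1.89 and 1.41, adjusted p 0.0851 and 0.0778), while rev_POC00483_1 was at -2.16; none of the 3 bounds holds on that scale.

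The mixture on day 7 differed from control at 1054 of 6523 probes, 769 higher and 285 lower, 605 of them at least 2-fold. POC00929_1 was higher, at 1.42 ± 1.55 (SD, n = 4; log2 difference 6.12, SE 1.37, limma adjusted p = 0.00711). It was well above background on 1 of 3 controls, and its log2 difference ran from 4.40 with normexp to 7.93 without control 1. POC03576_1 rose 16.1-fold, from -2.90 ± 0.40 (SD, n = 3) to 1.12 ± 0.51 (SD, n = 4; log2 difference 4.01, SE 0.42, limma adjusted p = 1.37e-05). rev_POC02323_1 was at least 2.74-fold lower (-3.44, SE 0.35, limma adjusted p = 1.00e-05) and POC03047_1 at least 3.72-fold lower (-3.82, SE 1.11, limma adjusted p = 0.0276); with normexp POC03047_1 was at -1.44 (adjusted p = 0.0855), under that bound, and it passed in 6 of 12 settings without left-out arrays. POC03576_1 and rev_POC02323_1 passed under every alternative run for them, with each array left out in turn included; with normexp their log2 differences were 3.41 and -1.47. POC03047_1 was lost without any 1 control or without mixture replicate 3 or 4 (adjusted p 0.0530 to 0.0816). Its probe is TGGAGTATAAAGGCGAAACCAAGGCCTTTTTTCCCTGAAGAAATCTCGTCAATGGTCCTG, and that of POC03576_1 is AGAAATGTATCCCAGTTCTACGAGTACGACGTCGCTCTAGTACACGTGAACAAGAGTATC. The count was 1114 with slide as a block, under which POC03047_1 was not called (-3.30, adjusted p = 0.141), 434 in the fit to these 7 arrays (POC00929_1 not among them, adjusted p = 0.0595), 623 with mixture replicate 4 counted as typical and 629 without control 2. With normexp the median of all probes was -0.13 and the split 436 higher and 360 lower, and 666 of the 769 higher probes lay above 0.

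**Figure D1:**
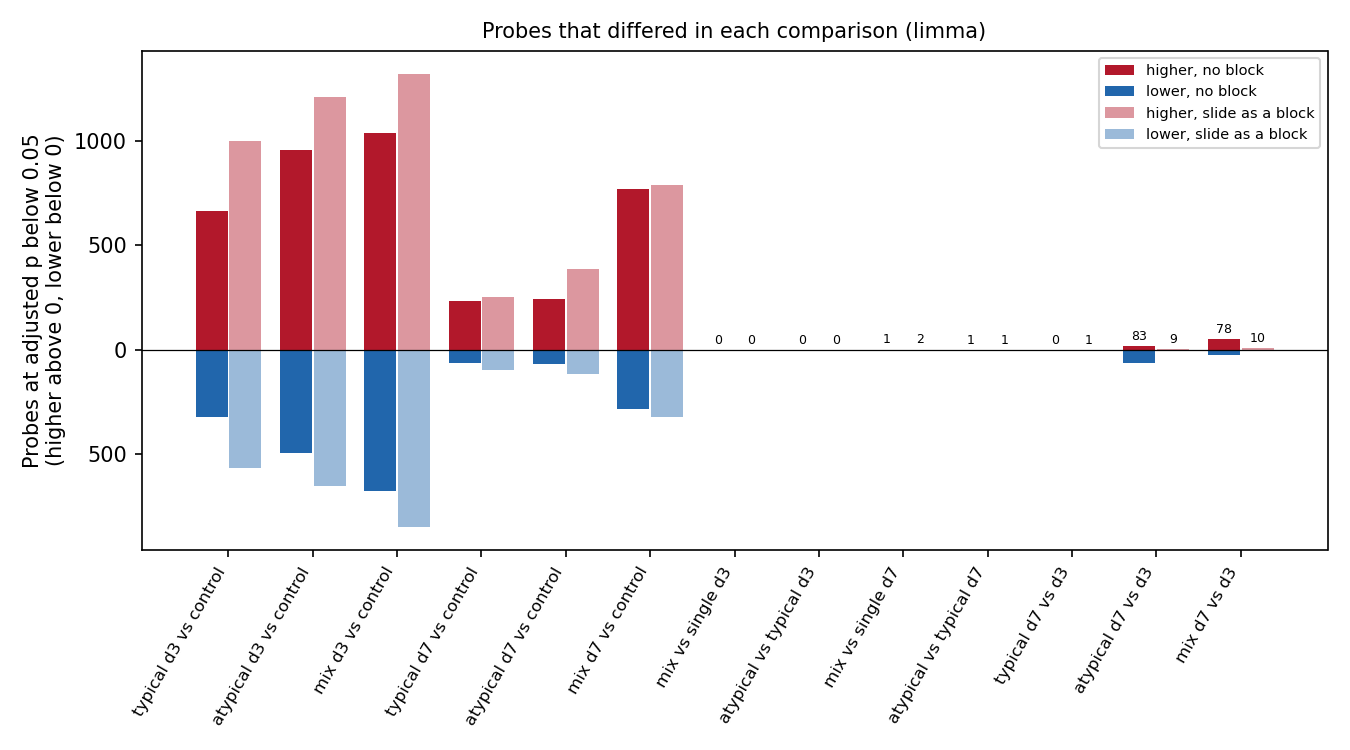
Number of probes called higher (above 0) or lower (below 0) at limma adjusted p under 0.05 in 13 comparisons, without a block (dark bars) and with slide as a block (pale bars); totals under 100 are printed. Comparisons with control run from 298 to 1715 probes, and comparisons between vaccines hold 0 or 1 without the block; with normexp background correction, lower calls outnumbered higher calls in 5 of the 6 comparisons with control.

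The 3 vaccines were compared in which probes differed from control. On day 3, 549 probes were called higher with all 3 vaccines and 231 lower; on day 7 these numbers were 147 and 39, and 112 and 34 were called higher or lower in all 6 comparisons. Of the 2263 probes called in any of the 6, 2 were called in opposite directions. Across probes, log2 differences from control correlated at r = 0.830 (typical and atypical), 0.818 (typical and mixture) and 0.858 (atypical and mixture) on day 3. On day 7 the values were 0.758, 0.814 and 0.794. All comparisons share the 3 controls, and unchanged groups simulated against such controls gave 0.496 to 0.537 for these 6 pairs. The covariance was 0.839, 0.927 and 1.02 on day 3 and 0.487, 0.545 and 0.568 on day 7, against 0.164 to 0.170 in the simulation. Typical and atypical calls on day 3 overlapped at 586 higher probes, where independent lists would share 97.3, and at 263 lower probes, where they would share 24.8. For atypical and mixture the overlap was 804 (151) and 363 (51.7). The 3 controls cannot be split into parts of 2, so part of these overlaps may come from the shared controls. Probes are not independent replicates.

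A direct comparison of the mixture with the mean of both single vaccines asked whether the mixture acts differently. On day 3, 0 of 6491 probes passed (limma; 377 at unadjusted p under 0.05, where 325 would come by chance). Within slide 1 and with slide as a block it was also 0. On day 7, 1 of 6504 probes passed (398 at unadjusted p under 0.05): AB080611, named because the count is that small. It kept a value on 1 of 3 day 7 atypical arrays, replicate 3 at -7.44, while the outlier-marked spots of replicates 1 and 2 read 3.37 and 3.01. With those spots kept, its adjusted p went from 4.98e-04 to 0.862 (log2 difference 1.45) and the count was 0; without day 7 atypical replicate 3 it was also 0, without replicate 2 of that group 4, and on day 3 it was 4 without mixture replicate 1. With slide as a block 2 probes passed on day 7, and 0 within slide 2. In simulated data of this design, 44 of 100 probes changed by 1 log2 and 84 of 100 changed by 2 log2 were recovered on day 3, and 51 and 83 on day 7. The number of arrays limits what smaller differences could be detected.

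Between the atypical and typical vaccines, 0 of 6524 probes passed on day 3 (limma), and the count was also 0 within slide 1 and with slide as a block. At unadjusted p under 0.05 there were 222 probes, where 326 would come by chance. On day 7, 1 of 6519 passed (164 at unadjusted p under 0.05), again AB080611, with a log2 difference of -10.36 (adjusted p = 2.39e-05) that became -3.29 (adjusted p = 1.00) with its outlier-marked spots kept. Without day 7 atypical replicate 3 the count was 0 and without replicate 2 it was 4. Slide as a block left 1 and the test within slide 2 gave 0. The 164 probes on day 7 also lay below the 326 that would come by chance. Simulated changes of 1 log2 were recovered for 35 of 100 probes on day 3 and 41 of 100 on day 7. For changes of 2 log2 these were 83 and 76 of 100. The simulated noise was independent and held no slide or pool effects, so these recoveries need not hold for the real arrays.

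Change over time was tested for each vaccine. For the typical vaccine, 0 of 6533 probes differed between day 7 and day 3 (limma; 598 at unadjusted p under 0.05, 327 by chance); slide as a block gave 1. For the atypical vaccine 83 of 6493 differed, 18 higher and 65 lower on day 7. POC03703_1 fell 10.1-fold between the days, from -1.42 ± 0.32 to -4.76 ± 0.24 (SD, n = 3 each; log2 difference -3.34, SE 0.54, limma adjusted p = 0.0225; -2.31 with normexp), with controls at -3.96 ± 0.87 (SD, n = 3). POC04534_1 fell 6.35-fold (-2.67, SE 0.47, limma adjusted p = 0.0225). POC00524_1 rose 3.93-fold (1.98, SE 0.44, limma adjusted p = 0.0468) and rev_POC01741_1 was at least 1.13-fold higher (1.97, SE 0.32, limma adjusted p = 0.0225; 0.78 with normexp), well above background on 2 of 3 day 7 arrays. The 4 calls were lost without day 3 replicate 1 or 2 or day 7 replicate 1 or 3, that of POC00524_1 also without day 7 replicate 2 and that of POC04534_1 also without day 3 replicate 3 (adjusted p 0.0591 to 0.154). The probes read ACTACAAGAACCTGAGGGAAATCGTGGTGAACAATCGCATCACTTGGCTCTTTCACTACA for POC03703_1, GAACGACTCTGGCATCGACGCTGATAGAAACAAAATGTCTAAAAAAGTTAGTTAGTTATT for POC04534_1, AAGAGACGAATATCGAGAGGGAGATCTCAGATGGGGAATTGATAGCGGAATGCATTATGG for POC00524_1 and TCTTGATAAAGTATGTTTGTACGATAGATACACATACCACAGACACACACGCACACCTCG for rev_POC01741_1. The days share only slide 3, where each group has 1 array, and with slide as a block 9 probes were called and none of these 4 (adjusted p 0.0538 to 0.201). With replicate number as a block the count was 186, in the fit to these 6 arrays 2, with weight 2 for pools 342, with no filter 17, with the stricter filter 163, with the authors' values 26, with mixture replicate 4 counted as typical 20 and with outlier spots kept 127. Leaving out day 3 replicates 1, 2 and 3 in turn gave 1, 1 and 17 probes, and day 7 replicates 1, 2 and 3 gave 1, 13 and 3. Normexp called 11 higher and 19 lower and quantile normalization 28 higher and 44 lower.

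For the mixture 78 of 6532 probes differed between the days, 51 higher and 27 lower on day 7. rev_POC01823_1 was higher on day 7, going from -6.38 ± 1.87 (SD, n = 3) to -3.21 ± 0.93 (SD, n = 4; log2 difference 3.17, SE 0.74, limma adjusted p = 0.0455). It was well above background on 1 of 3 day 3 arrays, and its log2 difference ran from 1.66 with normexp to 4.22 without day 3 replicate 1. rev_POC04042_1 rose 6.77-fold (2.76, SE 0.65, limma adjusted p = 0.0468; 1.90 with normexp), well above background on 2 of 3 day 3 arrays. AB362423 was at least 6.13-fold lower (-3.47, SE 0.68, limma adjusted p = 0.0320; -1.46 with normexp, under that bound) and POC03703_1 fell 5.03-fold (-2.33, SE 0.50, limma adjusted p = 0.0348). The 4 calls were lost without day 3 replicate 3 or day 7 replicate 1, 2 or 3, that of rev_POC01823_1 also without day 3 replicate 2 and those of rev_POC04042_1 and POC03703_1 also without day 3 replicate 1 or 2 (adjusted p 0.0589 to 0.151). The probe of rev_POC01823_1 is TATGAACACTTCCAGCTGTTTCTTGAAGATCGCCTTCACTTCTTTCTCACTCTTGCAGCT and that of AB362423 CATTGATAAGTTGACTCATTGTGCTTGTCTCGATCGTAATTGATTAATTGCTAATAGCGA. With slide as a block 10 probes were called, and rev_POC01823_1 (adjusted p = 0.141), rev_POC04042_1 (0.261) and POC03703_1 (0.194) were not; the fit to these 7 arrays and the fit with weight 2 for pools called 0, normexp 50, no filter 10, the stricter filter 126, mixture replicate 4 counted as typical 188 and outlier spots kept 149. Leaving out day 3 replicates 1 and 3 gave 30 and 0 probes, and day 7 replicates 1, 2, 3 and 4 gave 0, 5, 0 and 306. Quantile normalization gave 37 higher and 38 lower. The mixture contrast itself differed between the days at 1 of 6416 probes (248 at unadjusted p under 0.05), again AB080611 (5.26, adjusted p = 0.0134), and at 0 with its outlier-marked spots kept. That count was 0 without day 3 typical replicate 2 or 3, day 3 mixture replicate 2 or 3, day 7 atypical replicate 3 or day 7 mixture replicate 1 or 2, and 3 without day 3 mixture replicate 1 or day 7 atypical replicate 2.

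**Figure D2:**
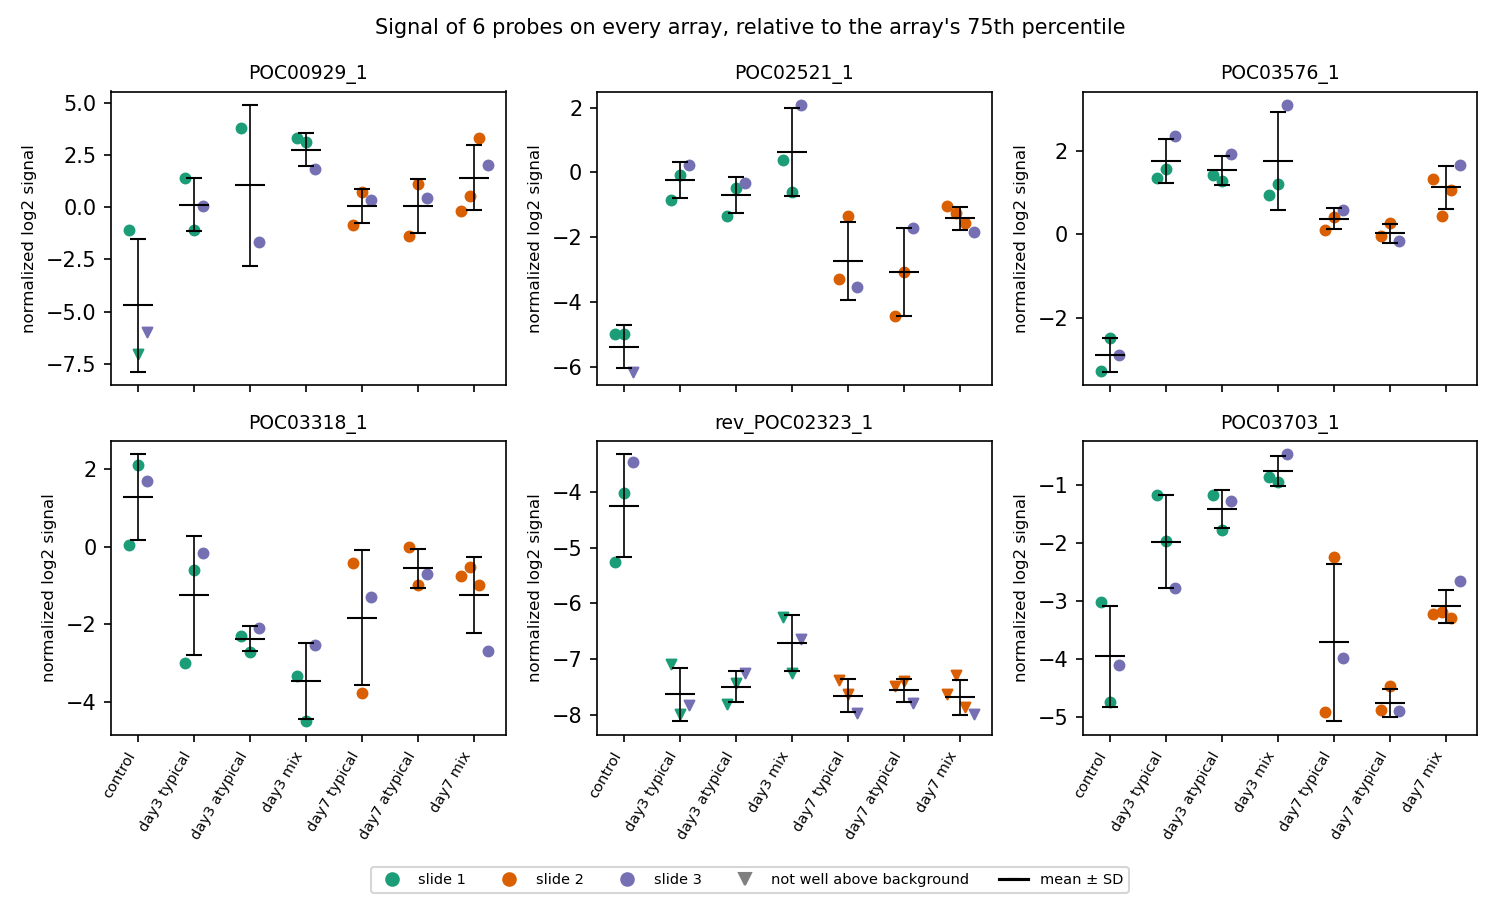
Log2 signal of 6 named probes on each of the 22 arrays, relative to the array's 75th percentile, by group. Points are arrays coloured by slide, triangles are arrays where the probe was not well above background, and bars give the mean and SD; POC02521_1 lies at -5.37 in controls and -0.23 on day 3 after the typical vaccine, and POC03703_1 lies at -1.42 on day 3 and -4.76 on day 7 after the atypical vaccine.

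Slide 3, which held 1 single-fish array per group, gave a separate look at the calls made on the other slides. Calls made without slide 3 had the same direction in its vaccinated and control arrays for 436 of 494 probes (88.3%) for the typical vaccine on day 3, 732 of 810 (90.4%) for the atypical vaccine and 844 of 889 (94.9%) for the mixture. On day 7 the numbers were 176 of 201 (87.6%), 242 of 262 (92.4%) and 952 of 1142 (83.4%). These day 7 calls set controls on slide 1 against vaccinated arrays on slide 2, so vaccine and slide are not separated in them. Over all probes, called or not, the shares were 69.6%, 72.0% and 75.3% on day 3 and 65.2%, 64.7% and 73.0% on day 7, in the same order. These values have no test, since slide 3 has no replicates.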

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

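Of the tests in this part, those on the response score and on replicate 4 of the day 7 mixture were chosen after their results were seen; the counts of other splits were planned.

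Each array was given a score: the mean of the 549 probes called higher on day 3 with all 3 vaccines minus the mean of the 231 called lower, relative to controls. In the day 7 mixture, replicates 1 to 3 scored 2.23, 2.21 and 2.20 and replicate 4 scored 3.12. That gap filled 0.964 of the group's range, above the critical value of 0.829 for 4 arrays. Of 23 such tests 3 passed it; chance gives about 1 in 20. All 23 were in this group, since no other has 4 arrays. The others were rev_POC04042_1 (0.874), where replicate 3 at -1.72 stood apart, and POC03703_1 (0.830), where replicate 4 did at -2.67.

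The mean score of the 4 day 7 mixture arrays was 0.66 above that of the 6 single-vaccine arrays of that day, although typical replicate 2 scored 2.26, above mixture replicates 1 to 3 (2.44 ± 0.45, n = 4, against 1.83 ± 0.49 for typical and 1.72 ± 0.33 for atypical, n = 3 each; exact two-sided permutation p = 0.0333 over 210 splits). With quantile normalization 98.5% of the difference was left, again at an exact permutation p of 0.0333. With normexp the difference was 0.50 at an exact permutation p of 0.0238. The percentile scaling takes 1 constant from each array, which cancels in a score that subtracts 2 means of the same array. The quantile result is therefore no test of that scaling. Replicate 4 may account for part of it: without that array 66.1% was left, 0.44 at an exact p of 0.119. Within slide 2, 77.7% was left, 0.52 at an exact p of 0.20, so neither replicate 4 nor slide can be told apart from a difference between vaccines with so few arrays. The mixture arrays were single fish and 4 of the 6 others pools, and a difference between vaccines stays open.

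The source name of replicate 4 gives the typical vaccine, so a wrong label is a candidate explanation for its distance from the other mixture arrays. It scored 0.85 above the highest day 7 typical array, less than that group's range of 0.957. The day 7 typical arrays averaged 1.83, below the 2.21 of mixture replicates 1 to 3, though typical replicate 2 reached 2.26. Replicate 4, at 3.12, lay on the other side. Taking it as typical would widen the distance rather than account for it, and the score does not settle which label is right. Replicate 4 was also the only day 7 mixture array on slide 3. There the single-vaccine arrays lay above their slide 2 mates by 0.15 (typical) and 0.32 (atypical), on average 25.8% of replicate 4's excess of 0.90, so an effect of slide cannot be told apart from a difference of this array, with 1 array per group there. A difference between fish was not tested.

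The change from day 3 to day 7 is the difference of both days' effects against the same controls. By that test, without a block, 83 probes passed for the atypical vaccine and 78 for the mixture. The days share only slide 3; with slide as a block 9 and 10 passed, and of the probes named here AB362423 alone. For the atypical vaccine POC00524_1 (1.98) and rev_POC01741_1 (1.97) were higher on day 7, and POC03703_1 (-3.34) and POC04534_1 (-2.67) lower. For the mixture rev_POC01823_1 (3.17) and rev_POC04042_1 (2.76) were higher and AB362423 (-3.47) and POC03703_1 (-2.33) lower. The difference of the mixture contrast between the days passed at 1 probe, AB080611.

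Counts of calls were set against other splits of the same arrays. For the mixture on day 7 against control, 1 of 35 splits, the real one, gave as many as 1054, and the highest other gave 52. That is the smallest share 35 splits allow, and it was not corrected for the number of comparisons. The real split also sets controls on slides 1 and 3 against mixture arrays on slides 2 and 3, so it does not separate vaccine from slide. With 10 splits no share under 0.05 can be had. In these the real values and highest others were 991 and 0 (typical, day 3), 1451 and 0 (atypical, day 3), 1715 and 4 (mixture, day 3), 298 and 4 (typical, day 7), 313 and 6 (atypical, day 7) and 83 and 2 (atypical, day 7 against day 3), each with 1 split as large. They were 0 and 2 for atypical against typical on day 3 and 0 and 1 for typical on day 7 against day 3, where all 10 splits must reach 0 and nothing was tested, and 1 and 1 for atypical against typical on day 7 (3 splits). Chance cannot be excluded for the mixture against the single vaccines on day 7 (43 of 100 splits reached 1; highest other 2) or for the difference of that contrast between days (30 of 100; highest other 3).

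In 2 comparisons another split gave many more calls than the real one, 455 against 0 and 282 against 78. For the mixture against single vaccines on day 3 the real count was 0, which all 84 splits must reach, so the number of splits tests nothing. The split of the 3 single-fish arrays on slide 3 from the 6 pools on slide 1 gave 455, which points to a structure of the samples by slide or pooling. With slide as a block the real count stayed at 0. For the mixture on day 7 against day 3, 2 of 35 splits reached 78. The other one, with 282, set day 7 replicates 1 to 3, all on slide 2, against the day 3 arrays and day 7 replicate 4. It keeps most of the day contrast and parts the slides too, so it separates neither chance nor slide from day. With slide as a block the real count was 10.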

How the results depend on the processing

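The alternatives with outlier spots kept, at least 2 values per group, slide-wise tests and slide block with quantile normalization were chosen after seeing the data. Of 403 values of named probes under settings other than left-out arrays, 325 stayed past the threshold in the same direction, 78 did not pass and 0 reversed; with an array left out these were 120, 80 and 0 of 200. Correlations between responses stayed within their spread under quantile normalization, slide as a block and outlier spots kept. Comparisons are given below as typical, atypical and mixture; unless a cause is named, it was not tested. Dim probes limit all folds, since 54.8% to 67.5% of probes per array were well above background. Set tests, their block variants and the mean of probes per gene were not run, since no probe has a gene name.

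Fitting only the compared groups, with fewer arrays, gave 215, 929 and 868 probes on day 3 and 0, 22 and 434 on day 7 against control, 2 for mixture against single vaccines on day 7, 0 for atypical against typical on day 7, and 2 (atypical) and 0 (mixture) for day 7 against day 3. Within slide 1 the day 3 counts were 507, 834 and 923, and within slide 2 both vaccine comparisons gave 0. Slide as a block gave 1567 (typical, day 3), 504 (atypical, day 7), 2 (mixture against single, day 7) and 1, 9 and 10 for the 3 day changes; with quantile normalization too it gave 1595, 1 and 2 (mixture against single, day 3 and day 7), 1, 3 and 3 for the day changes and 0 for the difference of the mixture contrast. Weight 2 for pools gave 1522 (typical, day 3), 488 and 560 (typical and atypical, day 7), 342 and 0 (atypical and mixture day change). Mixture replicate 4 counted as typical gave 719 and 623 (typical and mixture, day 7) and 1, 20 and 188 for the day changes.

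Normexp gave 506 (atypical, day 7), 30 and 50 (atypical and mixture day change) and 0 for the difference of the mixture contrast. Against control it kept 413 of 667, 614 of 957 and 662 of 1038 higher calls on day 3. It turned 1, 2 and 8 of these to lower calls. On day 7 it kept 109 of 232, 139 of 243 and 414 of 769. Lower calls kept were 320 of 324, 489 of 494 and 664 of 677 on day 3 and 56 of 66, 67 of 70 and 239 of 285 on day 7. No probe filter gave 17 and 10 for those day changes, and the filter on all arrays 163 and 126, with 0 for mixture against single and atypical against typical on day 7 and for the contrast difference. Quantile normalization gave 3 (mixture against single, day 7) and the authors' values 26 (atypical day change). Outlier spots kept gave 127 and 149 for the day changes. With those spots kept, or with at least 2 values per group, the counts for both day 7 vaccine comparisons and the contrast difference were 0.

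Replicate numbers as a block gave 480 (atypical, day 7), 2 (mixture against single, day 7), 3, 186 and 415 for the typical, atypical and mixture day changes, and 0 for the contrast difference. The check of pairing was met for the atypical day change, typical against control on day 3 (1268 with the block) and atypical against typical on day 7 (1); the block changed no other call of these by over 1.5 times. In the other comparisons the samples share only a number.

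Leaving out 1 array at a time gave 574 to 962, 916 to 1248 and 1216 to 1762 probes on day 3 against control, and 117 to 267, 162 to 268 and 629 to 954 on day 7. Mixture against single gave 0 to 4 on day 3 and 0 to 4 on day 7, atypical against typical 0 to 0 on day 3 and 0 to 4 on day 7, the day changes 0 to 0, 1 to 17 and 0 to 306, and the contrast difference 0 to 3.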

Other observations

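Of the tests in this part, those on the probes that vary together were written before their results were seen, although the set itself had been noticed while exploring the data.

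Many contigs are covered by a probe in each orientation, and for 49.4% of tested contigs both passed the filter. Within pairs that both passed, the median level difference between orientations was 5.56 log2, so 1 probe was often far dimmer. Of 4683 contigs with both, 2083 had both probes past the filter, and 1667 the forward and 466 the reverse probe alone. On day 3 after the mixture, both probes were called for 253 of 1952 pairs, where independent calls would give 133, and 251 of these moved the same way. After the typical vaccine on day 3 it was 119 of 1966 (43.3 by independent calls), 118 in the same direction. Across pairs the log2 differences correlated at 0.521 to 0.667 in the 6 comparisons with control. Which orientation is the transcript's sense was not analysed here.

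Among the 300 probes that varied most within groups, of 3785 with values well above background on all arrays, 5 clusters held at least 10 probes. The largest held 51, POC03318_1 among them, and 50 of them were called in at least 1 of the 6 comparisons with control. Of all 6729 probes kept, 2263 were. The set's mean level was 0.60 to 1.49 on control arrays, -3.34 to -0.28 on day 3 arrays and -2.42 to 0.61 on day 7 arrays. Since its probes vary together, their calls are not separate results. Their mean differed by 3.03 log2, 8.18-fold, between day 7 typical replicates 1 and 2, pools of 2 fish each on the same slide. Noise of single spots is argued against by the reverse probes of the same contigs: 22 such probes, not used to choose the set, correlated with it at a median r of 0.712 over the 22 arrays, 18 of them over 0.4 and the lowest at -0.673. Differences between slides held 2.39% of the variance of the set's mean deviation from group means. Slides 1 and 2 hold no group in common, so removing group means takes out part of any slide effect, and this share does not exclude slide. The mean deviation of single-fish arrays was 0.645 of that of pools (95% bootstrap interval 0.361 to 1.12). Deviations that are independent between fish would be larger on single-fish arrays than on pools. This ratio cannot decide on them: its interval reaches 1.12, and deviations were taken from means of groups that mix pools and single fish. Outside the day 7 mixture, single fish also lay on slide 3 alone. The largest deviations were those of the pools day 7 typical replicates 1 and 2 (1.36 and -1.67). What the probes of the set share stays open, since they have no gene names.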
